A study of Danio rerio with 15 samples.

How the data were processed

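Cells were profiled by droplet single-cell RNA sequencing with 10x Genomics 3′ libraries. They came from the microdissected jaw joint of adult zebrafish aged 3 to 6 months, after complete resection of the joint. Live cells had been sorted before loading. The fish carried fluorescent transgenes, and no reporter sequence was among the genes of the files. The 15 libraries fell into 7 groups: uninjured fish, fish taken 1, 3 or 7 days after the joint was resected, and fish taken after 14, 28 or 70 days. Times are given as dpjr, days past joint resection. The uninjured group held 3 libraries, 1 pooled and 2 from single animals. Each other group held 1 pooled library and 1 from a single animal. Per the labels, the libraries of 1, 3 and 7 dpjr and the first single uninjured animal formed batch 1, and the remaining 8 libraries formed batch 2. Beyond the words pooled and single animal, nothing in the labels says how separate the replicates were, so p-values measure only the spread between these libraries.

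The deposited files hold UMI counts per gene and cell barcode, made by the authors with Cell Ranger. Per the file headers this was version 6.1.2, and the submitters' processing notes name GRCz11 as the genome. The count tables held 32520 genes with 31771 different symbols, and 13 mitochondrial genes. Genes are named by their symbols in the files, and genes that share a symbol were kept apart. No reads were realigned and no gene positions were given in the tables.

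Tables were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Of 158559 barcodes, 116143 had at least 300 detected genes and under 20% mitochondrial UMIs. Simulated doublets were scored in each library, and 1692 cells above a score of 0.25 were removed, which left 114451 cells. Counts were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes were scaled with a limit of 10 SD and reduced to 40 principal components (scikit-learn 1.9.0). Cells were joined to 20 nearest neighbours and grouped by the Leiden method at resolution 1 (igraph 0.11.9, leidenalg 0.10.2). This gave 33 clusters, numbered from 0.

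Clusters were named from 25 marker lists fixed before the data were examined, of whose 267 genes 254 were measured. A cluster was assigned the list with the highest mean log2 fold among those with at least 3 markers above a log2 fold of 1 and detected in over 10% of its cells. The fold was taken over the median cluster with a pseudocount of 20 CPM. It kept that name where no other list had more markers among its 10 leading genes, counting genes detected in over 20% of its cells. The doublet threshold, this scoring rule and the makeup of the connective set were settled after the data had been seen, when 8 definitions of the fold had been compared. Under these, 23 of 33 clusters kept their name throughout, 8 kept it under some definitions, and clusters 1 and 2 under none. Clusters with over 80% of their cells from 1 library were kept apart by number, a rule also set after seeing the data. These were cluster 0 (13841 cells, 91.0% from the pooled library of 3 dpjr, median 1114 UMIs in that cluster), cluster 20 (1811 cells, 91.9% from the pooled uninjured library) and cluster 31 (418 cells, 87.3% from the pooled library of 3 dpjr). They led with the connective, epithelial and neutrophil lists in that order. The named classes were epithelial, neutrophil, macrophage, T or NK, osteoclast, osteoblast, chondrocyte, cycling, endothelial, mural, glia and muscle progenitor cells. Clusters 22 and 28 stayed unnamed.

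The connective set was the sum of the clusters assigned to the connective, tenocyte or joint lining list that did not come mostly from 1 library, namely clusters 1, 2, 3, 5, 6, 13, 15 and 29. Clusters 5, 6 and 13 were named connective and cluster 29 tenocyte. Clusters 1, 2, 3 and 15 had among their 10 leading genes a marker of another list (dendritic, chondrocyte, mural or joint lining) and none of the connective list, and were kept by number within the set. Cluster 6 led with cygb1, tnfaip6 and lepa, so those genes served both to separate cells and to compare groups. The cycling cluster 18 held cygb1, tnfaip6 and adamtsl7 among its leading genes, as cluster 6 did, and was left out of the set. In the pooled library of 3 dpjr it held 1269 cells, beside 1738 of the connective set.

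Counts of a class were summed per library where it had at least 20 cells. Genes were filtered with filterByExpr and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, after TMM normalization, with group and batch as terms and all libraries in 1 fit. This left 7 residual degrees of freedom for the connective set. With the batch term, the contrasts of 1, 3 and 7 dpjr with uninjured fish rest on the 1 uninjured library of batch 1. The macrophage fit had 4 residual degrees of freedom and no batch term, because 1 uninjured library (the pooled one, 27 macrophages) passed the minimum. At 7 and 28 dpjr 1 library passed as well, and such a lone library was assumed to vary like the other groups. Macrophage contrasts within a batch were added after seeing the data. Cell class shares were tested with edgeR on cell numbers, with group and batch as terms and the library's cell total as offset. A second test took 10 skeletal and connective classes and clusters as the whole. All tests were two-sided, with Benjamini-Hochberg adjustment over all genes or all class and time pairs of a test, and a threshold of 0.05. CPM values of named genes are counts of a gene summed over a class in 1 library, per 1e6 counts of the filtered genes after scaling by the TMM factor, averaged over libraries. Folds from a fit with a batch term are adjusted for batch, and these means are not. So a fold can differ from the ratio of the CPM beside it. Plain CPM, without that factor, were used for single clusters, for chondrocytes and where col2a1a is compared between cell classes of a library.

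The rule for named genes, fixed before the data were examined, took among genes with an adjusted p below 0.05 and a mean log2 CPM of at least 5 the 5 with the largest rise and the 5 with the largest fall. In classes other than the connective set and macrophages it took 3 each way. It left out clone names and asked that both libraries of the group lie beyond all libraries they were compared with. A further 30 core genes of skeletal repair were followed throughout. Of these mmp13a was not among the tested genes under that symbol, so 29 were tested. A fitted fold against libraries without a single UMI of the gene is not a bound, so for such genes CPM values stand in place of the fold.

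In the connective set 17 gene lists and 6 marker lists of other cell types were tested, and 9 lists in macrophages, with camera (limma 3.58.1, preset correlation 0.01). The connective lists were fibrillar collagen and its assembly, provisional matrix, proteases and their inhibitors, cartilage, osteoblast, ligament and tendon, synovial joint, proliferation, acute inflammation, glycolysis and hypoxia, Wnt, TGF-beta and BMP, and Hedgehog, FGF and retinoic acid signalling, craniofacial and blastema transcription factors, contractile cytoskeleton, quiescent fibroblast and dissociation stress. The marker lists were those of macrophages, neutrophils, skeletal muscle, epithelium, endothelium and red blood cells. The last had fewer than 5 measured members and was not tested. The macrophage lists were acute inflammation, antigen presentation, lysosome, glycolysis and hypoxia, proliferation, interferon, osteoclast, repair ligands and iron handling. All lists were fixed before the data were examined. Each was repeated with a correlation estimated from the data.

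Depth varied from 4437144 UMIs in the first single uninjured animal to 94669794 in the pooled library of 1 dpjr. The connective set summed to between 1606728 UMIs (second single uninjured animal) and 32986806 (pooled, 28 dpjr), the macrophage class to between 106617 (pooled uninjured) and 8066798. The gene test was tested on simulated data drawn with the spread of these libraries. In the connective set at 1 dpjr it found 0% of 2-fold, 16.4% of 4-fold and 62.1% of 8-fold changes, with 1 false call among 53. At 28 dpjr it found 1.49%, 43.3% and 75.8% of them, with 3 false calls among 83. In macrophages at 1 dpjr it found 2.99% of 4-fold, 23.9% of 8-fold and 54.5% of 32-fold changes, with 2 false calls among 56. A class simulated at 0.1% of cells was found higher in 20%, 93% and 98% of 100 simulations at 16-fold, 64-fold and 128-fold. A cartilage list and a proliferation list doubled on simulated data were both found, with 0 false calls among 126 list tests. Simulated genes were drawn independently of each other, so this cannot show how often correlated genes give false list calls. So single genes that changed 2-fold were rarely detectable when few genes changed, as in these simulations, and small shifts in rare classes were not. Contrasts with many more calls have a looser cutoff. From 1 to 7 dpjr, with 3127 genes called in connective cells, col12a1a passed at a log2 fold of 1.085. Libraries of 1 group were checked for being the same cells read again: shared barcodes were at most 1.06%, and expression differed by a chi-square per degree of freedom of 15.8 to 56.2 in 9 pairs.

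Alternatives were no batch term, library type as a further term, DESeq2 1.42.0 on the same filtered genes, RLE size factors, no filter, a resolution of 1.5 (42 clusters), cells with at least 500 genes and under 10% mitochondrial UMIs, equal cell numbers (366 connective cells and 22 macrophages per library), batch 2 alone, doublets kept, limma on logit shares, and each library left out in turn. Added after the data had been seen were the connective set from named clusters alone, without cluster 6, with the cycling cluster 18 or with cluster 0, class shares without cluster 0, shares and compartment with cluster 0 counted as connective, and epithelial genes without cluster 8. Plots were drawn with matplotlib 3.10.9.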

Results

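Gene expression was measured in 114451 single cells of the zebrafish jaw joint from 15 libraries. The groups were uninjured fish (3 libraries) and 6 times from 1 to 70 days after the joint had been cut out (dpjr), with 1 pooled library and 1 from a single animal at each time. Total UMIs in the uninjured group were 55438849 in the pooled library (12406 cells), 4437144 in the first single animal (885 cells) and 6070843 in the second (849 cells). The pooled and the single-animal library held 94669794 and 17991468 UMIs at 1 dpjr, 57764344 and 32937955 at 3 dpjr, and 33213083 and 12090285 at 7 dpjr. They held 78767299 and 13841530 at 14 dpjr, 68645656 and 30261818 at 28 dpjr, and 51180102 and 18648940 at 70 dpjr. Cells per library numbered from 849 to 25607. The median depth was lowest in the pooled library of 3 dpjr, with 1201 UMIs per cell, and highest in the single animal of that time, with 7532.

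The first comparison asked which cell types were more or less frequent at each time than in uninjured joints. Neutrophils, the first phagocytes to reach a wound, made up 26.8% ± 15.0 of cells at 1 dpjr (SD, n = 2; 16.2% pooled and 37.4% single animal). In uninjured joints they made up 0.136% ± 0.146 (n = 3), with 0 of 885 cells in the uninjured library of batch 1, which allows up to 0.339%. They were still higher at 3 dpjr, at 1.97% ± 2.03. Cluster 31, which led with the neutrophil list, was not counted among them. In the pooled library of 3 dpjr it held 365 cells, against 136 counted as neutrophils. Macrophages, which engulf debris and present antigen, rose from 0.187% ± 0.0602 to 8.76% ± 0.687 at 1 dpjr and stood at 1.45% ± 0.558 at 14 dpjr, also past the test. Cells of a cluster defined by division genes rose from 0.00537% ± 0.00931 to 2.66% ± 0.337 at 1 dpjr and 5.63% ± 0.958 at 3 dpjr. The uninjured library of batch 1 held 0 of these among its 885 cells, which allows up to 0.339%. In edgeR the adjusted p were 0.00996 and 0.0405 for neutrophils at 1 and 3 dpjr, 0.0172 and 0.0289 for macrophages at 1 and 14 dpjr, and 0.0208 and 0.0137 for cycling cells at 1 and 3 dpjr. Macrophages at 3 dpjr (2.84% ± 0.444, adjusted p = 0.0503) did not pass. The call of neutrophils at 3 dpjr ended with doublets kept and in 8 of 15 omissions of a library, and that of macrophages at 14 dpjr ended in 5 of 15.

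Chondrocytes, which lay down cartilage matrix, made up 10.3% ± 1.26 of cells at 14 dpjr (n = 2) against 0.0591% ± 0.102 in uninjured joints (n = 3; edgeR, adjusted p = 0.00996). They stood at 2.14% ± 1.56 at 7 dpjr (adjusted p = 0.0503) and at 0.173% and 0.240% at 28 and 70 dpjr. All 22 uninjured chondrocytes came from the pooled library. The single animals held 0 among 885 and 849 cells, which allows up to 0.339% and 0.353%. Mural cells, which wrap small vessels, rose from 0.263% ± 0.0787 to 1.54% ± 0.271 at 14 dpjr (adjusted p = 0.0396). T or NK lymphocytes passed the test at 14 dpjr (3.49% ± 0.431, adjusted p = 0.0289), 28 dpjr (5.28% ± 2.13, 0.0137) and 70 dpjr (3.77% ± 1.08, 0.0244) against 1.66% ± 1.90. Their shares overlapped those of the uninjured libraries, and without the batch term the adjusted p were 0.315, 0.131 and 0.278. Osteoclasts, which dissolve bone, were 2.06% ± 1.91 and 1.41% ± 1.46 of cells at 1 and 3 dpjr (adjusted p = 0.0606 and 0.0716). In the uninjured libraries 0 of 12406, 885 and 849 cells were osteoclasts, which allows shares of up to 0.0242%, 0.339% and 0.353%. The osteoblast class, named by markers of bone-forming cells, was 10.3% ± 2.51 at 3 dpjr against 1.89% ± 0.578 (edgeR, adjusted p = 0.0658). The connective set, the fibroblast-like cells of the joint, was 55.3% ± 18 of cells in uninjured joints and between 26.4% (3 dpjr) and 78.4% (70 dpjr) after injury, without a call. Cluster 0, which led with the connective list, was left out of it and held 12590 of the 25607 cells of the pooled library of 3 dpjr. With it counted in, the share at 3 dpjr was 52.6%. Of 108 tests of a class at a time, 13 passed (12 higher, 1 lower), and 37 had an unadjusted p below 0.05. The 2 calls not named above were of cluster 0 at 3 dpjr (26.2% against 0.0269%, adjusted p = 0.0302) and of cluster 20, lower at 70 dpjr (0.0615% against 4.47%, adjusted p = 0.0463), each mostly from 1 library. The 13 calls became 6 without the pooled uninjured library, 29 without its first single animal, 32 without either library of 3 dpjr, 8 without the pooled library of 14 dpjr, and 7 and 8 without the pooled and the single-animal library of 70 dpjr. They became 21 with cluster 0 counted as connective. The mural call at 14 dpjr ended in 8 of 15 omissions, that of cluster 20 in 11, and those of T or NK cells in 6, 2 and 3 in order of time. The call of cluster 20 also ended without the batch term, with library type as a term, with doublets kept and with limma on logit shares.

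**Figure D1:**
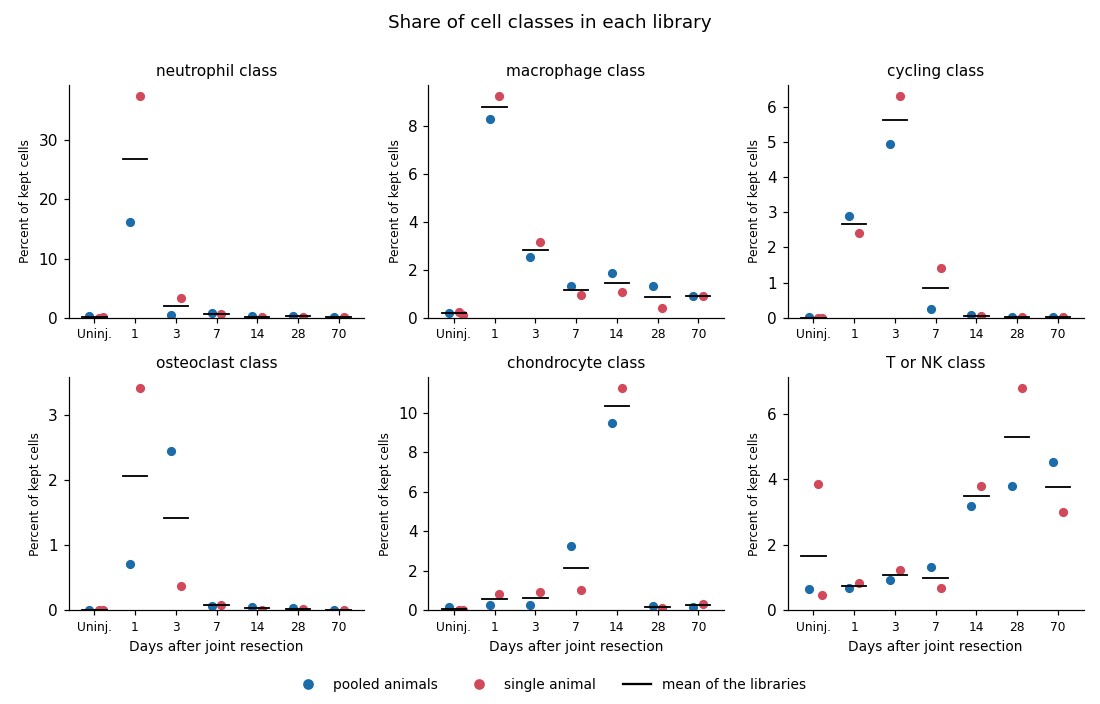
Share of cells of each class (y axis, percent) by time after resection (x axis, days), with 1 point per library and the mean of each group. Neutrophils stood at 26.8% at 1 dpjr and chondrocytes at 10.3% at 14 dpjr.

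A second test took skeletal and connective cells as the whole, so that immune and epithelial cells did not move the shares. Chondrocytes rose there from 0.119% ± 0.206 in uninjured joints (n = 3) to 1.92% ± 1.62 at 1 dpjr, 1.65% ± 0.117 at 3 dpjr, 3.27% ± 2.69 at 7 dpjr and 15.8% ± 2.66 at 14 dpjr (n = 2 each; edgeR, adjusted p = 0.0366, 0.0366, 0.0143 and 0.000122). At 28 and 70 dpjr they stood at 0.265% and 0.295%. With the batch term, the calls at 1, 3 and 7 dpjr rest on the first single uninjured animal, which held 0 chondrocytes. All 22 uninjured ones came from the pooled library, of batch 2. The class held little col2a1a at 1 and 3 dpjr, between 320.0 and 3181 plain CPM in those 4 libraries, against 32170 and 46110 at 14 dpjr. The osteoblast class rose from 3.57% ± 1.62 to 37.5% ± 24.2 at 3 dpjr (20.4% and 54.6% in its libraries, edgeR adjusted p = 0.0153). This class joins 2 clusters. Cluster 11 held 31.8% of the compartment at 3 dpjr against 0.0867%, and cluster 10 held 5.67% against 3.49% (adjusted p = 0.000145 and 0.353). Of cluster 11, 68.8% of cells came from the pooled library of 3 dpjr. Its leading genes were spp1 and col10a1a, but they also held cygb1 and CR855311.1, as those of cluster 6 did. So the rise of the class need not be one of bone-forming cells. In all, 15 of 60 tests passed (7 higher, 8 lower), with 22 at an unadjusted p below 0.05. The other 10 calls concerned clusters within the connective set, whose leading genes themselves differ between groups, as cluster 6 (76.8% and 45.2% at 1 and 3 dpjr against 0.113%). The chondrocyte calls at 1 and 3 dpjr ended with library type as a term, without the first single uninjured animal, without either library of 28 dpjr, and without the single animal of 1 dpjr or the pooled library of 3 dpjr in turn. That at 7 dpjr ended without its pooled library. With cluster 0 counted in the compartment, a choice made after seeing the data, osteoblasts were 16.2% at 3 dpjr and did not pass (adjusted p = 0.160). The chondrocyte calls at 1 and 3 dpjr then ended too (0.0856 and 0.145), and those at 7 and 14 dpjr held.

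Connective cells at 1 dpjr were compared with those of uninjured joints for genes of the early response. In each named gene that passed the test, here and at later times, both libraries of the time lay beyond every library they were compared with. The largest rises were in lepa, a zebrafish leptin, from 0.527 ± 0.10 to 266 ± 20.3 CPM (10, 1 and 1 UMIs in the uninjured libraries), saa, an acute-phase protein (log2 fold 6.83 ± 1.72 SE, 2.65 to 190 CPM), timp2b, an inhibitor of matrix proteases (6.38 ± 1.14, 41.4 to 1833 CPM), and prdm1a, a transcriptional repressor (6.09 ± 1.04, with 366, 3 and 17 UMIs in the uninjured libraries). The membrane protein gene ms4a17a.8 went from 20.4 ± 18.2 to 83.6 ± 3.51 CPM. The largest falls were in tppp3, a tubulin-binding protein found in tendon sheath cells (−6.80 ± 0.95, 133 to 1.97 CPM), mgp, an inhibitor of calcification (−5.15 ± 1.12), gyg1b, which primes glycogen (−5.15 ± 0.69), pah, which breaks down phenylalanine (−4.70 ± 0.68), and soul5 (−4.53 ± 0.47). The edgeR adjusted p of these 10 genes lay between 0.000277 and 0.0251. Of 29 core genes of skeletal repair, 5 rose. These were the tendon regulator scxa (2.75 ± 0.67), the protease mmp9 (6.02 ± 1.63), the division genes pcna (3.18 ± 0.44) and mki67 (0.427 ± 0.740 to 10.21 ± 1.69 CPM), and the retinoic acid enzyme aldh1a2 (2.40 ± 0.58). The 2 that fell were the matrix gene postnb (−2.58 ± 0.50) and the chemokine cxcl12a (−2.03 ± 0.50). Division genes were measured here and at later times in a set without the cycling cluster 18, which shared leading genes with cluster 6.

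In all, 3458 of 17986 genes passed at 1 dpjr (1899 higher, 1559 lower), and 6048 had an unadjusted p below 0.05. Without the batch term 5590 passed, of which 2979 were shared. The count was 1709 without the pooled library of 1 dpjr. Cluster 6, which lepa helped to define, held most connective cells of 1 and 3 dpjr. At 1 dpjr these were 4432 of 4722 in the pooled library and 350 of 409 in the single animal. Without cluster 6, and so with few cells of 1 dpjr left, the count was 446. The calls of lepa, saa, ms4a17a.8, tppp3, mgp, gyg1b, mmp9, pcna, mki67, aldh1a2 and postnb then ended, and those of timp2b, prdm1a, pah and soul5 held. Named clusters alone ended the calls of lepa, saa, tppp3, mmp9, scxa and cxcl12a, and equal cells those of mgp and mmp9. Without the batch term prdm1a stood at 2.84 and cxcl12a and ms4a17a.8 did not pass. Without the first single uninjured animal, the calls of ms4a17a.8, scxa and cxcl12a ended, without the pooled library of 1 dpjr those of saa, mmp9 and cxcl12a, without its single animal that of mgp, and without the single animal of 70 dpjr that of mmp9.

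Among the lists at 1 dpjr, proliferation rose, with 10 of 23 members higher over all genes and 15 adjusted over the list alone, none lower (camera, adjusted p = 1.68e-06). Its leading members were the replication licensing genes mcm2 (4.69 ± 0.59) and mcm6 (4.67 ± 0.61). Glycolysis and hypoxia rose, with 11 of 20 members higher over all genes and 13 adjusted over the list alone (adjusted p = 8.36e-05), led by the glycolytic enzyme pgam1a (3.38 ± 0.69) and the vessel growth factor vegfaa (2.49 ± 0.54). Genes of dissociation stress fell, 5 lower and 1 higher of 19 over all genes and 6 and 1 adjusted over the list alone (adjusted p = 0.00419). Of these the immediate early gene fosb fell (−2.90 ± 0.50) and the chaperone hspa8 rose (1.74). These lists had an adjusted p = 0.576, 0.672 and 0.868 with an estimated correlation. Macrophage and neutrophil markers, measured in the connective cells as a sign of RNA from other cells, had adjusted p of 0.0693 and 0.0644, with 2 of 13 and 1 of 11 members higher over all genes.

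Connective cells at 3 dpjr were compared with uninjured joints in the same way. Leptin lepa was far higher (367 ± 140 CPM, n = 2, against 0.527 ± 0.10, n = 3), as were prdm1a (log2 fold 6.05 ± 1.04 SE), the tendon matrix protein thbs4a (5.60 ± 1.36), the globin cygb1 (5.14 ± 0.54, 122 to 2540 CPM) and the tubulin tubb5 (4.61 ± 1.29). The enzyme genes gyg1b (−4.62 ± 0.67), pah (−4.01 ± 0.66) and tat (−3.82 ± 0.56), mgp (−4.19 ± 1.08) and the link protein hapln1a (−3.97 ± 0.66, 3085 to 235 CPM) fell most. Their edgeR adjusted p lay between 0.000938 and 0.0490, and cygb1 and lepa are also genes by which cluster 6 was set apart. Of the core genes, scxa (3.99 ± 0.69, 11.6 to 79.3 CPM), the fibronectin fn1b (4.1 ± 1.18, adjusted p = 0.0499), mki67 (9.52 ± 2.27 CPM), pcna (1.88 ± 0.42) and aldh1a2 (2.54 ± 0.58) rose, and cxcl12a fell (−2.58 ± 0.50). In all, 2011 genes passed (959 higher, 1052 lower), 5103 had an unadjusted p below 0.05, and 3823 passed without the batch term (1640 shared). The count was 1333 without the pooled library of 3 dpjr, 380 without its single animal and 27 without cluster 6. Without cluster 6 the calls of scxa, thbs4a, gyg1b, hapln1a, pah and tat and the other named genes bar cygb1 and cxcl12a ended. Named clusters alone ended the calls of lepa, gyg1b, mki67 and pcna, equal cells those of tubb5, mgp, fn1b and pcna, library type those of tubb5 and fn1b, and stricter cells that of fn1b. Without the single animal of 3 dpjr those of lepa, thbs4a, tubb5, mgp, fn1b, pcna and aldh1a2 ended, and without the first single uninjured animal those of mgp and cxcl12a. The calls of tubb5, mgp and fn1b ended in 8, 7 and 10 of 15 omissions. Those of prdm1a and scxa held in each, but their log2 folds went as low as 2.34 and 2.25.

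The list of fibrillar collagen and its assembly rose at 3 dpjr, with 2 of 24 members higher and 1 lower over all genes and 9 and 2 adjusted over the list alone (camera, adjusted p = 0.00411). The collagen hydroxylase p4ha2 (2.24) and the collagen gene col11a1a (3.25) rose, and the crosslinking enzyme loxl1 fell (−1.70). Proliferation (adjusted p = 2.81e-07, 9 of 23 higher over all genes and 14 adjusted over the list alone) and glycolysis and hypoxia (0.000289, 9 of 20 higher, 12 higher and 1 lower adjusted over the list alone) stayed up. Dissociation stress stayed down (0.0261, 3 lower and 1 higher of 19, and 6 and 1 adjusted over the list alone). In the order given, these 4 lists had an adjusted p = 0.868, 0.576, 0.733 and 0.877 with an estimated correlation.

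Connective cells at 7 dpjr were set against the same uninjured joints. The regulator scxa (log2 fold 4.02 ± 0.69 SE, as low as 2.29 in an omission, 11.6 to 81.2 CPM) and the tendon membrane protein tnmd (2.69 ± 0.54, 58.8 to 308 CPM) rose. So did the matrix proteoglycan aspn (3.52 ± 0.66), the secreted angptl2b (3.73 ± 0.73), arginase arg2 (3.51 ± 0.58) and the growth factor mdka (3.36 ± 0.68). The cartilage collagen col2a1a rose from 1.04 ± 0.560 CPM (n = 3) to 42.5 ± 21.0 (n = 2; 5.66 ± 0.93). In plain CPM the non-skeletal classes held a median of 25.7 of it in the pooled library, where connective cells held 26.1, and 0 in the single animal, where connective cells held 62.5. The genes clec3ba (−3.48 ± 0.56), olfml2ba (−3.30 ± 0.48), cxcl12a (−2.80 ± 0.50), the retinoic acid enzyme aldh1a3 (−2.60 ± 0.45) and tspan35 (−2.31 ± 0.36) fell. Adjusted p for these genes lay between 0.0252 and 0.0458 (edgeR). Each call ended without the single animal of 7 dpjr, and those of col2a1a, tnmd and angptl2b also with equal cells per library and with cluster 0. With named clusters alone the calls of all but mdka ended. That of mdka ended without cluster 6, with cluster 0 and with stricter cells, that of aspn without cluster 6 and that of angptl2b with stricter cells. Of 15 omissions, 12 ended the call of aspn, 11 that of mdka, 9 those of angptl2b and cxcl12a, 8 those of tnmd and aldh1a3, 6 those of scxa and clec3ba, 5 those of arg2 and tspan35, 4 that of col2a1a and 1 that of olfml2ba.

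At 7 dpjr 101 genes passed (38 higher, 63 lower), and 3051 had an unadjusted p below 0.05. Without the batch term 779 passed (75 shared), and in DESeq2 496. Each omission moved this count, to 53, 513 and 55 without the pooled, first and second single uninjured library, to 6 without either of 1 dpjr and to 463 and 4 without the pooled and the single-animal library of 7 dpjr. In the order pooled and single animal, it was 52 and 47 without those of 3 dpjr, 261 and 270 of 14 dpjr, 12 and 51 of 28 dpjr, and 10 and 23 of 70 dpjr. Fibrillar collagen and its assembly rose (camera, adjusted p = 6.51e-14), 1 of 24 members over all genes (col11a1b, 2.98 ± 0.54) and 17 adjusted over the list alone. Cartilage rose (2.29e-06), with 2 of 26 members higher, col2a1a and col2a1b (2.19), and 13 higher and 1 lower adjusted over the list alone. Ligament and tendon rose (6.16e-05), with 4 of 21 members higher, among them the proteoglycan ogna (3.14), and 8 higher and 1 lower adjusted over the list alone. These 3 lists had an adjusted p = 0.576, 0.576 and 0.600 with an estimated correlation. Free RNA of chondrocytes was not tested as a source of the rise in cartilage genes. Provisional matrix (0.0114; tgfbi 2.50; 1 higher, and 4 higher and 2 lower adjusted over the list alone), proliferation (0.00793; mcm6 3.12; 1 higher, 7 adjusted over the list alone), and glycolysis and hypoxia (0.0414; 0 and 0) passed as well. Markers of skeletal muscle, as a sign of RNA from other cells, rose too (0.0448; 1 of 10 higher under both adjustments, the troponin tnnt3b, 4.27 ± 0.71). In the order given, these had an adjusted p = 0.764, 0.868, 0.868 and 0.868 with an estimated correlation.

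**Figure D2:**
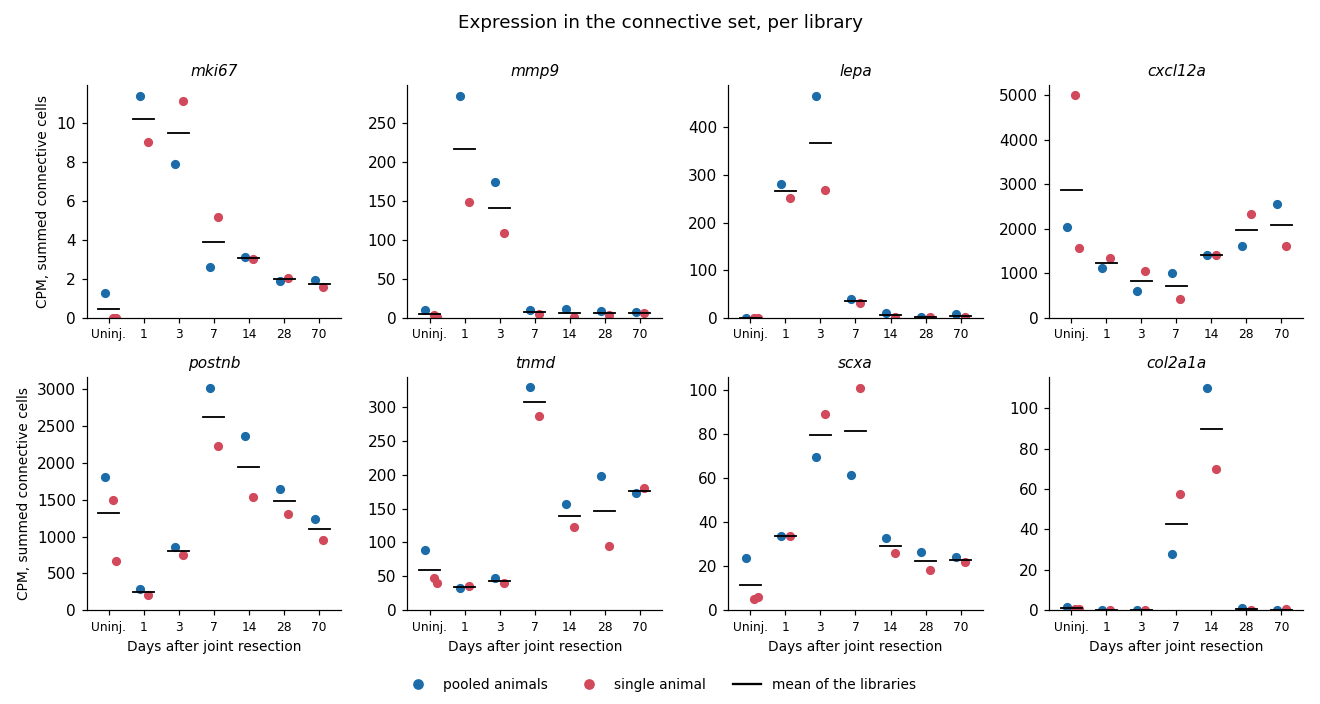
Level of named genes in connective cells (y axis, CPM) by time after resection (x axis, days), with 1 point per library and the group mean. The tendon regulator scxa stood at 11.6 CPM in uninjured joints and 81.2 at 7 dpjr, and col2a1a at 1.04 and 89.8 at 14 dpjr.

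At 14 dpjr 1 gene passed in connective cells, col2a1a, the main collagen of cartilage. It stood at 89.8 ± 28.3 CPM (n = 2) against 1.04 ± 0.560 in uninjured joints (n = 3; log2 fold 5.91 ± 0.57 SE; edgeR, adjusted p = 0.00253). In plain CPM the non-skeletal classes of the pooled library held a median of 149 of it and connective cells 108, and in the single animal 18.9 and 82.3. The call ended without the second single uninjured animal, with equal cells, with named clusters alone and with cluster 0. In all, 2039 genes had an unadjusted p below 0.05, and 240 passed in DESeq2. The count of 1 was 12, 5, 5, 2 and 58 without the pooled uninjured library, the pooled or single-animal library of 7 dpjr, and the pooled and single-animal library of 14 dpjr. At 28 dpjr 0 genes passed in edgeR, with 1399 at an unadjusted p below 0.05 and 74 passing in DESeq2. That count was 5 without the pooled uninjured library, 4 without either library of 7 dpjr and 1 without either of 14 dpjr. At 70 dpjr 11 genes passed (7 higher, 4 lower, 2132 at an unadjusted p below 0.05, 167 in DESeq2), none of which met the rule for named genes. Picked after their values were seen, the higher ones included the regulators foxo3b, tfap2a and lhx2b, the autophagy kinase ulk2, slc25a43 and paplnb. The lower ones were fjx1, daam1b, dlx4b and nfatc2a. That count was 32, 6 and 0 without the pooled, first and second single uninjured library, 0 without any 1 library of 1 or 70 dpjr, and 3 without either of 28 dpjr.

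The lists moved at the late times while few single genes passed. At 14 dpjr cartilage rose (camera, adjusted p = 6.51e-14), 1 of 26 members over all genes and 17 adjusted over the list alone, with col9a2 at 5.50 ± 1.05. Many of its members also mark chondrocytes, and free RNA of chondrocytes was tested as a source for col2a1a alone. Fibrillar collagen (5.27e-10, 9 of 24 adjusted over the list alone), ligament and tendon (1.09e-05, 9 higher and 1 lower) and provisional matrix (0.00397, 2 higher) rose without a member over all genes. These 4 lists had an adjusted p = 0.185, 0.576, 0.576 and 0.672 with an estimated correlation. Dissociation stress fell at 14 dpjr (4.97e-07, 4 of 19 lower adjusted over the list alone), and matrix proteases (0.0414, 2 higher) and proliferation (0.0249) rose, with an adjusted p = 0.713, 0.868 and 0.868 with an estimated correlation. Markers of macrophages (0.000109, grn1 at 4.62) and of skeletal muscle (2.06e-10, 8 of 10 higher adjusted over the list alone) rose in the same connective cells, with an adjusted p = 0.630 and 0.576 with an estimated correlation. At 28 dpjr fibrillar collagen (1.20e-10), ligament and tendon (5.90e-09, cilp at 1.68 ± 0.40), provisional matrix (0.00119) and cartilage (0.00381) rose, with 0 members over all genes and 4 and 6 members adjusted over the list alone in the first and second. These 4 lists had an adjusted p = 0.576, 0.576, 0.612 and 0.630 with an estimated correlation. Matrix proteases (0.0101), Wnt signalling (0.0301, the Wnt antagonist sfrp5 at 1.73), contractile cytoskeleton (0.0110) and markers of macrophages (0.0310) and skeletal muscle (2.32e-07, 6 of 10 adjusted over the list alone) rose as well. These 5 had an adjusted p = 0.858, 0.868, 0.868, 0.868 and 0.576 with an estimated correlation. At 70 dpjr ligament and tendon (0.000376, tnmd at 1.43), cartilage (0.0405), Wnt signalling (0.0414) and macrophage markers (0.0149) rose and proliferation fell (0.0431, 3 of 23 lower adjusted over the list alone), with an adjusted p = 0.632, 0.787, 0.868, 0.868 and 0.868 with an estimated correlation.

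Of 132 tests of a list at a time in connective cells, 37 passed, and 0 passed with an estimated correlation. Lists never past the threshold against uninjured joints, with their lowest adjusted p, were osteoblast (0.347), synovial joint (0.152), acute inflammation (0.0681), TGF-beta and BMP signalling (0.475), Hedgehog, FGF and retinoic acid signalling (0.116), craniofacial and blastema transcription factors (0.209) and quiescent fibroblast (0.0729). The same held for markers of neutrophils (0.0644), epithelium (0.325) and endothelium (0.486). Of acute inflammation, 4 of 23 members were higher at 1 dpjr over all genes, and the list passed at that time with stress and mitochondrial genes left out (adjusted p = 0.0173).

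Times of the same batch were compared in the same fit, without the uninjured libraries as a reference. Those libraries still entered the filter, the normalization and the estimate of spread. From 1 to 3 dpjr the collagen chaperone serpinh1b (log2 fold 2.42 ± 0.32 SE, 96.5 to 518 CPM, n = 2 each), the proteoglycan ogna (2.16 ± 0.43), the matrix proteins tgfbi (2.13 ± 0.33) and cilp (2.1 ± 0.42) and dock9b (1.88 ± 0.28) rose. The linker histone h1-10 (−2.69 ± 0.45), abi3bpa (−2.54 ± 0.31), the metalloreductase steap4 (−1.88 ± 0.36) and the nucleolar genes mybbp1a (−1.53 ± 0.22) and ncl (−1.41 ± 0.26) fell. Their edgeR adjusted p lay between 0.00426 and 0.0400, and 0 of 29 core genes passed. In all, 142 genes passed (53 higher, 89 lower), with 2497 at an unadjusted p below 0.05, 402 in DESeq2, and 4 without cluster 6, where abi3bpa turned (0.331) and all named calls but that of serpinh1b ended. The call of cilp ended with named clusters alone, those of cilp and ogna with the cycling cluster, those of cilp, ogna and tgfbi with cluster 0, and that of tgfbi without the batch term. Equal cells ended those of cilp, h1-10, steap4 and ncl. In the order pooled and single animal, the count was 13 and 6 without those of 1 dpjr, 26 and 4 of 3 dpjr, 297 and 284 of 7 dpjr, 284 and 267 of 14 dpjr, 35 and 36 of 28 dpjr, and 34 and 29 of 70 dpjr, and each named call ended in at least 1 omission. Fibrillar collagen (camera, adjusted p = 1.50e-07, 1 of 24 members higher over all genes and 6 adjusted over the list alone), ligament and tendon (7.73e-06, 2 and 5 of 21) and provisional matrix (0.00128) rose. These 3 lists had an adjusted p = 0.351, 0.321 and 0.345 with an estimated correlation. Acute inflammation (0.000809, il1b at −2.52) and markers of macrophages (0.000411, grn1 at −4.28) and neutrophils (0.000809) fell, each without a member over all genes. These 3 had an adjusted p = 0.567, 0.351 and 0.318 with an estimated correlation.

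Connective cells of 7 dpjr were set against those of 1 dpjr. The protease mmp9 fell by a log2 fold of 4.90 ± 1.03 SE (217 to 7.18 CPM, n = 2 each), saa by 4.99 ± 1.00, timp2b by 4.61 ± 0.75 (1833 to 74.7 CPM), adamtsl7 by 2.91 ± 0.34 and steap4 by 2.84 ± 0.38. Tendon and matrix genes rose, with tgfbi at 4.32 ± 0.36, cilp at 4.06 ± 0.45, tppp3 at 4.12 ± 0.83, tnmd at 3.16 ± 0.41 and postnb at 3.40 ± 0.46. The largest other rises were in adh8a, an alcohol dehydrogenase (4.82 ± 0.95), and prss35 (3.94 ± 1.06). Of 29 core genes 10 rose and 3 fell, and their edgeR adjusted p lay between 0.0000960 and 0.0487. Cartilage genes among them were col2a1a (7.09 ± 0.61, 0.253 to 42.5 CPM), acana (4.08 ± 0.90) and cnmd (3.73 ± 0.57). Free RNA of chondrocytes was not tested as a source of these rises. Genes past the threshold numbered 3127 (1366 higher, 1761 lower), with 5762 at an unadjusted p below 0.05. That count was 888 and 1974 without the pooled and the single-animal library of 1 dpjr, 1843 without the pooled library of 7 dpjr, 1749 with equal cells and 134 without cluster 6, where mki67 stood at 1.33, pcna at 0.230 and scxa at −0.179. Cluster 6 held 4432 of 4722 and 350 of 409 connective cells of 1 dpjr, so the fit without it rests on few cells of that time. Without cluster 6 the calls of mmp9, saa, adamtsl7, tppp3, prss35, acana, cnmd and the core genes scxa, sox9a, col1a1a, col12a1a, mmp2, mki67 and pcna ended. That of scxa also ended in 11 of 15 omissions, without the batch term and with cluster 0, and that of sox9a with named clusters alone. Omissions ended the calls of col12a1a and prss35 in 5 cases, those of sox9a, mki67 and mmp9 in 3, those of acana and tppp3 in 2 and that of col1a1a in 1.

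Lists of matrix genes rose and those of division and inflammation fell from 1 to 7 dpjr. Cartilage rose (camera, adjusted p = 1.27e-07, 16 of 26 members over all genes and 17 adjusted over the list alone), as did fibrillar collagen (7.00e-10, 14 and 19 of 24), ligament and tendon (1.34e-09, 11 and 14 of 21) and provisional matrix (0.000933, 10 higher and 1 lower over all genes). These 4 lists had an adjusted p = 0.212, 0.321, 0.235 and 0.334 with an estimated correlation. The rise in cartilage was not tested for free RNA of chondrocytes. Proliferation fell (6.50e-08, 11 and 13 of 23), as did glycolysis and hypoxia (0.000217, 10 and 12 of 20) and acute inflammation (0.00281, 6 lower and 1 higher over all genes, 9 and 1 adjusted over the list alone). These 3 lists had an adjusted p = 0.287, 0.355 and 0.619 with an estimated correlation. Dissociation stress rose (0.0236, 2 of 19 over all genes). Markers of macrophages (0.00382, 3 of 13 lower) and neutrophils (0.00296, 5 of 11 lower) fell and those of skeletal muscle rose (0.000544, 5 of 10 higher). These 4 had an adjusted p = 0.709, 0.497, 0.327 and 0.355 with an estimated correlation.

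Connective cells of 28 and 70 dpjr were set against those of 14 dpjr, where 1 gene passed, the cartilage collagen col2a1a. From 14 to 28 dpjr it fell by a log2 fold of 6.95 ± 0.55 SE to 0.589 ± 0.528 CPM, and from 14 to 70 dpjr it fell by 8.39 ± 0.62 to 0.299 ± 0.170 CPM (n = 2 each; edgeR, adjusted p = 0.000288 and 0.000116). In plain CPM it went from 108 at 14 dpjr to 0.940 at 28 dpjr in connective cells of the pooled libraries and from 82.3 to 0.215 in those of the single animals. The median of the non-skeletal classes went from 149 to 0 and from 18.9 to 0, while pooled macrophages, 1 of these classes, went from 92.6 to 315. Free RNA of chondrocytes was not tested as a source of this fall. No other gene passed, with 702 and 846 at an unadjusted p below 0.05 and 26 and 21 in DESeq2. Both calls ended with equal cells, with named clusters alone and with cluster 0. The first count was 4 without either library of 7 dpjr, the single animal of 14 dpjr or the pooled library of 28 dpjr, and the second 5 without either library of 7 dpjr and 17 without the single animal of 14 dpjr. Cartilage as a list fell at 28 dpjr (camera, adjusted p = 2.60e-12, 1 of 26 over all genes and 8 adjusted over the list alone) and at 70 dpjr (4.21e-11, 1 and 10). Both had an adjusted p = 0.117 with an estimated correlation. From 14 to 28 dpjr proliferation (2.33e-07) and macrophage (0.00995) and muscle markers (3.01e-05) fell, with an adjusted p = 0.287, 0.567 and 0.334 with an estimated correlation. Acute inflammation (0.00394), contractile cytoskeleton (1.81e-07) and dissociation stress (1.73e-07) rose, with an adjusted p = 0.629, 0.321 and 0.352 with an estimated correlation. From 14 to 70 dpjr fibrillar collagen (3.83e-10), provisional matrix (0.00128), synovial joint (0.00225) and proliferation (5.39e-09, 9 of 23 adjusted over the list alone) fell, with an adjusted p = 0.321, 0.334, 0.247 and 0.235 with an estimated correlation. Macrophage (0.0361) and muscle markers (3.83e-10) fell too, with an adjusted p = 0.619 and 0.235 with an estimated correlation. Acute inflammation (0.0253), contractile cytoskeleton (0.00291) and dissociation stress (3.83e-10) rose, with an adjusted p = 0.677, 0.352 and 0.321 with an estimated correlation. Of 88 such tests within a batch 34 passed.

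In macrophages at 1 dpjr 3 of 11 genes for antigen presentation were lower than in those of the pooled uninjured library. The invariant chain genes cd74a (log2 fold −7.83 ± 0.72 SE, 12106 to 52.6 ± 41.7 CPM) and cd74b (−5.95 ± 0.49) and the class II gene mhc2dab (−9.06 ± 0.84, 574 to 0.843 CPM) fell. The heat shock genes hsp70l (−5.55 ± 0.60) and hsp70.1 (−4.55 ± 0.55) fell too. Both are on the dissociation stress list, which was not tested in macrophages. Higher were grn1, a lysosomal growth factor precursor (4.52 ± 0.59, 856 to 19612 CPM), and the iron store gene fth1a (4.29 ± 0.61). Both libraries of 1 dpjr are of batch 1 and the uninjured one of batch 2, so batch and time cannot be told apart in these changes. These rest on 2 libraries against 27 cells of 1 uninjured library, in a fit without a batch term, with edgeR adjusted p between 0.000531 and 0.0154. At 3 dpjr mhc2dab stayed lower (−8.63 ± 0.94, adjusted p = 0.00950), the only gene of that contrast past the threshold. Counts were 13 of 6603 genes at 1 dpjr (4 higher, 9 lower, 958 at an unadjusted p below 0.05, 71 in DESeq2) and 1 at 3 dpjr (474 and 15). At 7, 14, 28 and 70 dpjr 0 passed in edgeR, with 318, 349, 271 and 329 at an unadjusted p below 0.05 and 1, 12, 1 and 2 in DESeq2. The count of 13 was 8 without the single animal of 1 dpjr, 49 and 60 without the pooled and single-animal library of 3 dpjr, 6 and 8 of 14 dpjr, and 7 without either of 70 dpjr. The count of 1 was 2 without the pooled library of 1 dpjr and 0 without any 1 library of 14 or 70 dpjr. That of 14 dpjr was 2 and 4 without the pooled and single-animal library of 3 dpjr and 1 without either of 70 dpjr, and that of 70 dpjr was 2 without either of 3 dpjr. The calls of mhc2dab, cd74a, cd74b and hsp70l at 1 dpjr held in all 10 omissions that gave a value, and those of hsp70.1, grn1 and fth1a each ended in at least 1. That of hsp70l ended at a clustering resolution of 1.5, and those of hsp70.1, fth1a and mhc2dab at 3 dpjr ended with equal cells.

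Macrophages of 3 dpjr were set against those of 1 dpjr, within batch 1. The invariant chain gene cd74a rose by a log2 fold of 4.90 ± 0.61 SE (52.6 ± 41.7 to 1590 ± 369 CPM, n = 2 each) and cd74b by 3.90 ± 0.42 (76.6 ± 15.3 to 1151 ± 495 CPM). The heat shock genes hsp70l (3.85 ± 0.52) and hsp70.2 (2.55 ± 0.41), both on the dissociation stress list, rose. The gene illr4, among the neutrophil markers (−4.14 ± 0.64, 115 to 6.71 CPM), and the respiratory chain gene cox6b1 (−2.45 ± 0.40) fell. The edgeR adjusted p of all these named genes lay between 0.00916 and 0.0455. In all, 11 genes passed (5 higher, 6 lower, 829 at an unadjusted p below 0.05), and from 1 to 7 dpjr 25 passed (19 higher, 6 lower, 823). From 14 to 28 and 14 to 70 dpjr 0 passed in edgeR, with 54 and 201 at an unadjusted p below 0.05 and 0 and 5 in DESeq2. The count of 11 was 4 and 1 without the pooled and single-animal library of 1 dpjr, 76 without the single animal of 3 dpjr, 3 without either of 14 dpjr and 5 without either of 70 dpjr. That of 25 was 15 and 12 without those of 1 dpjr, 56 and 63 of 3 dpjr and 13 without either of 70 dpjr, and the last count was 2 without the pooled library of 70 dpjr. Every named call ended in at least 1 omission, that of cd74b without the single animal of 1 dpjr alone and that of cd74a without any 1 library of 14 or 70 dpjr and under the stricter cell filter. That filter also ended the calls of hsp70l, hsp70.2, illr4 and cox6b1. Equal cells ended those of hsp70.2, illr4 and cox6b1, and a resolution of 1.5 those of hsp70l and hsp70.2.

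Of 54 list tests in macrophages against uninjured joints 11 passed, and 0 with an estimated correlation. Antigen presentation fell at 1 dpjr (camera, adjusted p = 5.59e-05, 3 of 11 lower over all genes, 4 lower and 1 higher adjusted over the list alone) and at 3 dpjr (0.000503, 1 and 3 lower). The lysosome list, genes of degradation and lipid handling, was higher at 1 dpjr (5.34e-07), with 1 of 18 higher over all genes and 6 adjusted over the list alone. It also passed at the 5 later times (1.50e-08, 0.0000156, 0.00155, 0.000753 and 0.000489 in order). All 6 calls share the same 27 uninjured cells, so an odd control alone could give them all, and at 7 and 28 dpjr 1 library stands against 1. At 1, 3 and 7 dpjr the batch differs from that of the control as well, so batch and time cannot be told apart. Glycolysis and hypoxia rose at 1 dpjr (0.000130, 3 of 20 adjusted over the list alone) and 70 dpjr (0.00656), and proliferation at 1 dpjr (0.00436). Each of these had an adjusted p = 0.693 with an estimated correlation. The lists of acute inflammation (lowest adjusted p = 0.445), interferon response (0.102), osteoclast (0.387), repair ligands (0.351) and iron handling (0.351) did not pass at any time. Within a batch 9 of 36 tests passed. Antigen presentation rose from 1 to 3 dpjr (0.0347, 2 higher over all genes and 3 adjusted over the list alone), from 1 to 7 dpjr (0.000800, 3 and 4, with cd74a at 7.22 and cd74b at 5.52) and from 14 to 70 dpjr (0.000782). Glycolysis and hypoxia fell from 1 to 3 (2.80e-07, 10 of 20 adjusted over the list alone) and from 1 to 7 dpjr (0.000663) and rose from 14 to 70 dpjr (0.00770), proliferation fell from 1 to 3 (0.000865) and 1 to 7 dpjr (0.00770), and lysosome fell from 1 to 7 dpjr (0.0224). Each of these had an adjusted p = 0.727 with an estimated correlation.

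Epithelial cells at 1 and 3 dpjr were of another mix than in uninjured joints. Cluster 8 held 2059 and 92 of them at 1 dpjr and 2137 and 98 at 3 dpjr (pooled and single animal), against 8, 0 and 1 in the uninjured libraries. The membrane protease adam8a stood at 166 ± 58.9 CPM at 1 dpjr and 142 ± 12.5 at 3 dpjr (n = 2 each) against 0.851 ± 0.846 in uninjured joints (n = 3; edgeR, adjusted p = 0.00229 and 0.00655). At 1 dpjr fn1b (log2 fold 7.98 ± 1.49 SE, 9.30 to 3233 CPM, adjusted p = 0.0403) and the actin-linked marcksl1a (6.54 ± 0.98) rose. The glycolysis regulator pfkfb3 (−3.51 ± 0.51), the amine oxidase aoc2 (−3.45 ± 0.47) and slitrk6 (−3.39 ± 0.57) fell. At 3 dpjr the autophagy gene vmp1 rose (5.66 ± 0.97), and slitrk6 (−3.12 ± 0.57), the transcription factor fosl1a (−3.01 ± 0.46) and atp6v0e1 (−2.95 ± 0.54) fell. Of 16419 genes 147 passed at 1 dpjr (82 higher, 65 lower, 2776 at an unadjusted p below 0.05) and 21 at 3 dpjr (8 higher, 13 lower, 2137), and 1213 and 451 without the batch term. Without cluster 8, a choice made after seeing the data, the counts were 158 and 7, and the calls of fn1b at 1 dpjr and vmp1, slitrk6 and fosl1a at 3 dpjr ended. At 7, 14, 28 and 70 dpjr 0 passed in edgeR, with 984, 1013, 1250 and 1447 at an unadjusted p below 0.05. In T or NK cells 1 of 4329 genes passed at 3 dpjr, zgc:158463, picked after its value was seen, and 0 without the batch term. It was 0 at 14, 28 and 70 dpjr, with 721, 115, 155 and 204 at an unadjusted p below 0.05. No other tool and no omission was run for these classes.

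**Figure D3:**
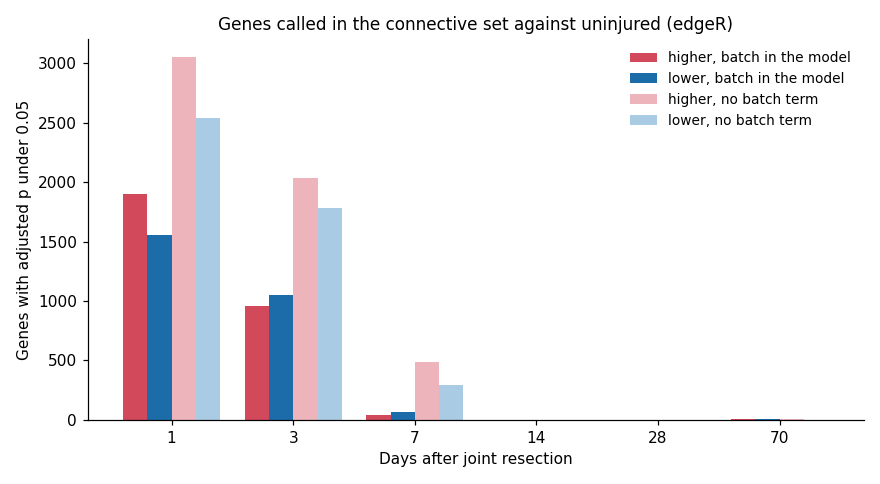
Number of genes higher and lower than in uninjured joints in connective cells (y axis, genes past an adjusted p of 0.05) at each time after resection (x axis, days), from edgeR. At 1 dpjr 1899 were higher and 1559 lower, and at 28 dpjr 0 passed.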

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

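Of the tests below, that of free RNA for cd74a was chosen only after the result was seen. The others were written before their own values, though related values (counts from 1 to 7 dpjr, CPM of cd74a) had been seen. For the list of genes here, only the 29 tested core genes were looked at. Those listed stood out because the change from uninjured joints differed between 2 times of a batch, by edgeR's test of the difference itself. From 1 to 7 dpjr 3127 of 17986 genes passed that test, so the kinds of genes listed reflect the core list. From 1 to 7 dpjr in connective cells, higher were the cartilage genes col2a1a (log2 difference 7.09), sox9a (1.29), acana (4.08) and cnmd (3.73) and the tendon genes scxa (1.27) and tnmd (3.16). The matrix genes col1a1a (1.78), col12a1a (1.085), postnb (3.40) and mmp2 (2.06) were higher too. Lower were mmp9 (−4.90), mki67 (−1.42) and pcna (−2.03). Of these, scxa lost its call in 11 of 15 omissions and without the batch term, col12a1a in 5 omissions, sox9a in 3 and with named clusters alone, mki67 and mmp9 in 3, acana in 2 and col1a1a in 1. Without cluster 6 the calls of all but col2a1a, tnmd and postnb ended, and scxa (−0.179), mki67 (1.33) and pcna (0.230) turned. That fit held few connective cells of 1 dpjr. From 14 dpjr, col2a1a was lower at 28 dpjr (−6.95) and at 70 dpjr (−8.39). No group held enough libraries for a rule on single libraries that stand apart, and no data outside the count tables were present.

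The cartilage collagen col2a1a was higher in connective cells at 14 dpjr, the time with the highest share of chondrocytes among the 7 groups. Free RNA from chondrocytes was tested by the ratio of connective CPM to the median of non-skeletal classes, which was 0.725 in the pooled library and 4.36 in the single animal. A few chondrocytes or doublets within the connective set were tested by the share of its col2a1a UMIs in the richest 5% of cells, which was 55.8% in the pooled library and 88.0% in the single animal. The ratios point different ways. The shares decide nothing, because only 22.5% and 8.75% of connective cells held a UMI of the gene, so the share below 25% set beforehand was out of reach in the single animal and nearly so in the pooled library. In the pooled library 22% of epithelial and 21.35% of T or NK cells held a col2a1a UMI as well. So connective cells showed little excess over these 2 classes there by share of cells, which was not matched for depth. By plain CPM they lay above epithelial cells and macrophages (108.2 against 44.07 and 92.57). They lay below T or NK, endothelial, mural and glial cells (198.2, 153.9, 144.6 and 157.5). In the single animal the shares of epithelial and T or NK cells with a UMI were 7.65% and 1.27%. Over both libraries neither source can be told apart from expression by connective cells, and the time after resection stays open and untested as a source.

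At 1 dpjr 3458 genes passed in connective cells, in contrasts that rest on 1 uninjured library of the same batch. To test batch or that library as the whole cause, genes were called without the single animal of 1 dpjr, which was then set against both 7 dpjr libraries of its batch. It lay beyond both in the called direction in 88.2% of the 2654 genes called, against 37.8% as the mean over all tested genes, which neither batch nor the control can give as the whole cause. Leak of neutrophil and macrophage RNA, at the share their own markers gave (0.0695% to 0.216%), covered at least 50% of the rise in 0.159% of the 1892 genes called higher with a higher mean CPM, so it was not the whole cause either. A change with time after resection, and the different makeup of the set (76.8% of the compartment in cluster 6 at 1 dpjr), remain open, and a biological source is a hypothesis.

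In macrophages cd74a was lower at 1 dpjr than at 3 dpjr, within batch 1. Free RNA from other cells of the 3 dpjr libraries was tested by the connective level, which was 0.749% of the macrophage level in the pooled library and 0.0341% in the single animal, far too low to be the source. A few cells of another type would give the UMIs to few cells, but with cells thinned to 500 UMIs 33.1% (647 cells, median 1203 UMIs before thinning) and 40% (75 cells, 4397) of 3 dpjr macrophages had one, against 3.07% (1205 cells, 5072) and 0.595% (168 cells, 8050) at 1 dpjr. In connective cells, which should lack the gene, the thinned shares were 0.748% and 0% at 3 dpjr (median 4092 and 11520 UMIs) and 0.402% and 0% at 1 dpjr. Another mix of macrophage subtypes and a change within them were not tested, and the pattern is a hypothesis at most.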

How the results depend on the processing

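The connective set from named clusters alone, without cluster 6, with the cycling cluster and with cluster 0, the class shares without cluster 0, shares and compartment with it counted as connective, and epithelial cells without cluster 8 were chosen after seeing the data. Depth was lowest in the macrophage class, with 106617 UMIs in its 1 uninjured library, and the T or NK class was close, with 129829 in the first single uninjured animal. No paired analysis was possible because the labels give no number that joins libraries of different groups. The pooled and single-animal kinds entered as library type. Among single genes and classes, leaving out a library left 7246 values the same, 326 lost and 144 gained their call, and 5 turned. The batch term left out gave 471 same, 8 lost, 37 gained and 3 turned. DESeq2 gave 310 same and 25 gained, equal cells 303 same, 22 lost and 6 gained, and the set without cluster 6 276 same, 46 lost, 1 gained and 4 turned. A value with no call in either setting counts as the same here, even where its sign changed. So these tallies do not give the share of calls that held. In connective cells 11 of 17 named calls at 1 dpjr, 8 of 16 at 3 dpjr and 13 of 22 from 1 to 7 dpjr held in each omission. None did at 7 dpjr against uninjured joints or from 1 to 3 dpjr, nor in macrophages from 1 to 3 dpjr. Not run were batch 2 alone for 1, 3 and 7 dpjr, macrophages against uninjured joints with stricter cells or without the pooled uninjured library, and 7 or 28 dpjr macrophages without their only library. Leaving out dissociation stress and mitochondrial genes kept the list counts within 1.5 times, and acute inflammation in connective cells at 1 dpjr then passed (adjusted p = 0.0173). Except where fewer cells, genes or libraries went in by construction, the cause was not tested.

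Counts of genes are given for the 6 times against uninjured joints and for 3 or 7 against 1 dpjr and 28 or 70 against 14 dpjr. Without the batch term, connective counts were 5590, 3823 and 779 at 1, 3 and 7 dpjr, and 25 class shares passed. With library type, connective 14 dpjr gave 32, and macrophages gave 121, 5, 8 and 1 at 1, 3, 7 and 28 dpjr, 251 for 3 against 1, 116 for 7 against 1, 2 for 28 against 14 and 3 for 70 against 14. With DESeq2, connective cells gave 496, 240, 74 and 167 at 7, 14, 28 and 70 dpjr, 402 for 3 against 1, 26 for 28 against 14 and 21 for 70 against 14. Macrophages gave 71, 15, 1, 12, 1 and 2 at the 6 times, 51 for 3 against 1, 68 for 7 against 1 and 5 for 70 against 14. RLE size factors gave 214 connective genes for 3 against 1. With no filter, which changes how many genes are tested, connective cells gave 3052, 1202, 681, 451 and 584 from 3 to 70 dpjr, 765 for 3 against 1, 210 for 28 against 14 and 280 for 70 against 14. Macrophages gave 233, 31, 13, 27, 13 and 16, then 293, 150, 4 and 13 in the order above. At resolution 1.5, connective cells gave 4 at 14 dpjr, 3 for 28 against 14 and 8 for 70 against 14, macrophages 24 at 1 dpjr, 18 for 3 against 1 and 41 for 7 against 1, with 22 shares and 27 compartment calls. With stricter cells, 70 dpjr gave 2, and macrophages 2 for 3 against 1. With equal cells, connective cells gave 10, 1 and 4 at 14, 28 and 70 dpjr, 46 for 3 against 1, 1749 for 7 against 1 and 0 for 70 against 14, and macrophages 21 and 0 at 1 and 3 dpjr and 1 for 28 against 14. Batch 2 alone gave 5 and 8 at 14 and 28 dpjr, 6 for 28 against 14 and 3 for 70 against 14.

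Named clusters alone gave 1316, 690, 19, 0 and 2 at 1, 3, 7, 14 and 70 dpjr, 254 for 3 against 1, and 0 and 0 for 28 and 70 against 14. Without cluster 6 the counts were 446, 27, 2 and 4 at 1, 3, 14 and 28 dpjr, 4 for 3 against 1, 134 for 7 against 1 and 2 for 28 against 14. With the cycling cluster, 3 against 1 gave 67. With cluster 0 they were 0 and 4 at 14 and 70 dpjr, 77 for 3 against 1, and 0 and 0 for 28 and 70 against 14. Limma on logit shares and shares without cluster 0 gave 25 and 25 calls. With cluster 0 counted as connective, shares gave 21 calls and the compartment 12, where osteoblasts at 3 dpjr (adjusted p = 0.160) and chondrocytes at 1 and 3 dpjr (0.0856 and 0.145) lost their call. Without cluster 8 epithelial cells gave 158 and 7 genes at 1 and 3 dpjr. With an estimated correlation 0 connective and 0 macrophage lists passed. Values that turned were cnmd at 1 and 3 dpjr (−2.45 and −2.35 without the batch term, −2.85 and −2.74 without the first single uninjured animal, with highest values of 0.963 and 1.19 in other omissions), and sox9a at 1 and 3 dpjr (2.39 and 2.73) and clec3ba at 7 dpjr (0.0878) with named clusters alone. Without cluster 6, and so with few connective cells of 1 dpjr, abi3bpa for 3 against 1 (0.331) and scxa (−0.179), mki67 (1.33) and pcna (0.230) for 7 against 1 turned. The share of cluster 20 turned at 1 dpjr (−9.27) without the batch term. In omissions it ranged from −9.85 to 2.44 at 1 dpjr and from −5.63 to 7.14 at 3 dpjr, lowest without the first single uninjured animal, and from −7.78 to 5.16 at 70 dpjr, highest without the pooled uninjured library.

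With 1 library left out in turn, class share calls ranged from 6 to 32 and compartment calls from 10 to 17. Connective counts ranged from 1709 to 4821, 380 to 2939, 4 to 513, 0 to 58, 0 to 5 and 0 to 32 at the 6 times, then 4 to 297, 888 to 3701, 1 to 4 and 1 to 17. Macrophage counts ranged from 6 to 60, 0 to 2, 0 to 0, 0 to 4, 0 to 0 and 0 to 2, then 1 to 76, 12 to 63, 0 to 0 and 0 to 2. Where this left 1 library in a group, it was assumed to vary like the other groups.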

Other observations

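Chondrocytes of different times held different amounts of their main collagen, a comparison picked after the values were seen and not tested. Per library, col2a1a stood at 23830 CPM in uninjured joints (22 cells), 3181 and 2888 at 1 dpjr (42 and 15 cells), 320.0 and 3074 at 3 dpjr (69 and 22), 36500 and 27740 at 7 dpjr (136 and 14), and 32170 and 46110 at 14 dpjr (1363 and 234). At 28 dpjr it stood at 18440 and 34940 CPM (32 and 5 cells) and at 70 dpjr at 4493 and 3194 (17 and 14). The osteoblast class held 2 clusters of unlike makeup. In cluster 10 the bone matrix genes bglap and ifitm5 stood at 2988 and 1597 CPM, and the maturing cartilage and bone collagen col10a1a at 33960 CPM. In cluster 11, the one that held more cells at 3 dpjr, they stood at 145 and 232 CPM, col10a1a at 3326 CPM and osteopontin, spp1, at 1768 CPM, against 1005 CPM in cluster 10.

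The genes prg4b and gdf5 had no call against uninjured joints in connective cells, though the synovial joint list fell from 14 to 70 dpjr (camera, adjusted p = 0.00225, and 0.247 with an estimated correlation). Lubricin prg4b, which coats the joint surface, stood at 299.5 ± 336 CPM in uninjured libraries (n = 3), 74.5 ± 45.1 at 1 dpjr, 88.3 ± 67.3 at 3 dpjr, 27.4 ± 31.0 at 7 dpjr, 318 ± 435 at 14 dpjr, 249 ± 193 at 28 dpjr and 86.3 ± 39 at 70 dpjr (n = 2 each; edgeR, lowest adjusted p = 0.391). The joint-forming signal gdf5 stood at 1.02 ± 0.736 CPM in uninjured libraries and at most at 0.959 ± 0.171 after injury. For col10a1a the level was 6.46 ± 11.2 CPM in uninjured libraries, where 2 of 3 held 0 UMIs, and 105 ± 19.5 CPM at 7 dpjr (adjusted p = 0.329). Muscle progenitors stood at 1.91% ± 2.47 of cells at 3 dpjr and 1.11% ± 0.0125 at 7 dpjr against 0.104% ± 0.0975 (adjusted p = 0.0879 and 0.138), and endothelial cells at 2.68% ± 0.379 at 3 dpjr against 0.535% ± 0.474 (adjusted p = 0.486).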
